A study of Mus musculus with 8 samples.

How the data were processed

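Mouse livers were compared between control mice, which carry floxed Tgfbr1 alleles, and Tgfbr1 MKO mice, which carry the same alleles and LysMcre, a Cre recombinase expressed from the myeloid Lyz2 locus. All mice had been fed a MASH diet, which models metabolic dysfunction-associated steatohepatitis, for 30 weeks. Bulk RNA-seq covered 3 control and 3 MKO livers. Single-nucleus RNA-seq covered 1 library per genotype, each a pool of 3 livers. The pooled samples were taken as the nucleus libraries because the deposited table of nuclei uses their labels. Per the labels' protocols, nuclei came from frozen liver, were stained with propidium iodide, sorted and processed on the 10x Genomics Chromium system, and bulk RNA was extracted from frozen tissue.

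Per the submitters' processing notes, the tools were FastQC, STAR, RSEM 1.3.3, DESeq2, Cell Ranger and Seurat 4.0.1 with the mm10 build; their roles, settings and gene annotation are not given in the sources used here. The bulk values deposited by the authors are a signal on a linear scale, gene counts divided by 1 size factor per library. Every value was a whole multiple of what 1 read is worth in its library (0.963 to 1.22), so whole reads were recovered for 100% of values within a tolerance of 0.01. The recovered reads per library lay between 17448117 and 23986319 over 15283 listed genes. The deposited table also holds the authors' own log2 fold changes and p-values, used here only to set counts of calls side by side. The nucleus values deposited by the authors are a signal too: a mean per gene, cluster and genotype, with each of the 26 columns summing to 10000. Clustering, the number of nuclei, filters, doublet removal and how the averages were formed are not given in the sources used here, so the depth behind a cluster mean is unknown and no interval was given for it.

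Because the bulk values are normalised, the test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1), with genotype as the only term, over the 15249 genes with a mean value of at least 1, which left out 34 genes. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Recovered reads were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 as alternatives. Apart from their replicate numbers, nothing in the labels says that the 3 libraries of a genotype came from separate animals, so p-values measure the spread between these samples. Each pair of libraries differed by more than sampling noise (chi-square per degree of freedom 28.1 to 73.1), so no library was counted as a duplicate. Reads may be split uncertainly among near-identical genes of the Fcgr, Cd300, Sirpb1, Ighg, Gbp, Ms4a, Ifit, H2, Saa and haemoglobin families, since the counting settings are unknown.

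Gene lists for cell types, pathways and handling checks were fixed before the data were examined. The 33 lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over lists), and camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. Named genes followed a rule fixed before the data were examined. It took Tgfbr1, then up to 10 called genes with the largest change in each direction, an official-looking symbol and groups that do not overlap. From each list it took up to 4 called members with the smallest p or, where none was called, the member with the highest mean. In the nuclei it took Tgfbr1 in each cluster, the 8 highest and 8 lowest ratios in the macrophage-like cluster, 3 and 3 elsewhere, and up to 4 members of each of 7 lists in the macrophage-like cluster. In the report, genes outside this rule are said to be so where their values are given, and 2 genes that the rule takes are not reported here.

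The nuclei have 1 pool per genotype, so no test was possible. The log2 ratio of MKO over control was taken for genes whose larger value reached the 90th percentile of non-zero larger values in a cluster, with a pseudocount of 1/10 of that percentile (0.144 in the macrophage-like cluster). A list's median was described by its percentile among 10000 random lists matched on mean expression in 10 bins. A cluster was called after a cell type only where at least 3 of that type's fixed markers were enriched by 2-fold or more over the other clusters and its leading genes did not go against the name.

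The bulk tests were tried on simulated libraries of the same depth with 200 changed genes. In 15240 genes limma recovered 2 of 67 genes changed 1.5-fold, 32 of 67 changed 2-fold and 50 of 66 changed 4-fold, with 9 false calls; edgeR and DESeq2 made 8 and 22. With no change simulated, limma made 0 calls, edgeR 1 and DESeq2 14. In 2000 simulated nucleus values, a list of 20 genes shifted by 1 on the log2 scale reached percentile 100 and an unshifted one percentile 71.4. Alternatives covered the scaling, the test, the filter, the pseudocount, the threshold, a replicate block and each library left out in turn. Positions are mm10 coordinates of GENCODE vM21, which matched 98.55% of the tested symbols (15028 of 15249). Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.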

Results

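Liver RNA was measured in control mice and in Tgfbr1 MKO mice, whose floxed Tgfbr1 alleles meet a myeloid Cre recombinase, after 30 weeks on a MASH diet. The comparison asks how loss of the TGF-beta type I receptor from myeloid cells alters the liver and its macrophages. Bulk libraries held 20638906, 23673147 and 21629449 recovered reads in control 1 to 3 and 17448117, 20559531 and 23986319 in MKO 1 to 3. The nuclei came as 1 pool of 3 livers per genotype, averaged over 13 clusters. The first principal component of the bulk values (36.4% of the variance) separated the genotypes, with controls from -43.0 to -20.4 and MKO livers from 24.4 to 41.2. On the second (20.8%) MKO 1 stood apart at 48.5, against -23.0 to 4.67 for the other libraries.

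Tgfbr1 (chromosome 4, 47353222 to 47414931, + strand) was read at 737, 810 and 777 in the control livers and at 560, 857 and 735 in the MKO livers. The means were 775 ± 36.6 and 717 ± 149 (SD, n = 3 each), a log2 fold change of -0.13 ± 0.16 (SE; limma adjusted p = 0.816), and 0.04 without MKO 1. The floxed exon is not given in the sources used here, so reads over the whole gene may not show the deletion. Whole liver also holds Tgfbr1 transcripts of cells that the Cre does not target. Within the macrophage-like nuclei the value was 13.5 in the control pool and 4.87 in the MKO pool.

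Bulk MKO livers had higher levels of Fcrl5, Fcgr4, Cd300e and Itgad and lower levels of Trem2 and Cx3cr1. Of 15249 genes tested with limma, 452 rose and 13 fell in MKO livers. Fcrl5, an Fc receptor-like gene (chromosome 3, 87435773 to 87500678, + strand), rose from 2.49 ± 2.20 to 96.8 ± 33.7, a log2 fold change of 5.07 ± 0.62 (adjusted p = 0.00502). Fcgr4, an activating receptor for IgG (chromosome 1, 171018920 to 171029761, + strand), rose from 75 ± 26.7 to 1162 ± 300.2, 15.7-fold (log2 fold change 3.98 ± 0.30, adjusted p = 0.00186). Cd300e, a myeloid receptor (chromosome 11, 115051917 to 115062177, - strand), rose from 28.0 ± 21.7 to 486 ± 99, and Itgad, an integrin alpha chain (chromosome 7, 128154376 to 128223816, + strand), from 3.78 ± 0.997 to 95.8 ± 17.8. Log2 fold changes from 3.84 to 4.38 were found for Ifit1bl1, Negr1, Pdcd1lg2, Krt80, Sirpb1c and Adamdec1. Of these 10 genes Pdcd1lg2 lost its call without MKO 3 (adjusted p = 0.0569), and the others held in all 6 fits with 1 library left out. Splits of reads among the Fcgr, Cd300, Sirpb1 and Ifit families are uncertain.

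Among the 13 genes that fell was Trem2, a lipid receptor of macrophages (chromosome 17, 48346401 to 48354147, + strand), from 71.4 ± 11.3 to 15.0 ± 4.64 (log2 fold change -2.20 ± 0.29, limma adjusted p = 0.00604). Another was Cx3cr1, a chemokine receptor of monocytes and macrophages (chromosome 9, 119901616 to 120069879, - strand), from 69.2 ± 12.9 to 11.8 ± 5.11 (-2.52 ± 0.35, adjusted p = 0.00691). Immunoglobulin heavy chain constant genes also fell, with log2 fold changes of -3.20 for Ighg2c, -2.76 for Ighg2b and -1.81 for Igha. The split between Ighg2b and Ighg2c reads is uncertain. Their sum went from 181 ± 87.1 to 21.6 ± 5.59. Osgin1, a gene induced by oxidative stress (chromosome 8, 119434124 to 119446256, + strand), fell from 8974 ± 507 to 4387 ± 1251, and Gclc, an enzyme of glutathione synthesis, from 11261 ± 760.5 to 6107 ± 1414. Smaller decreases were found for Cpeb2 (-0.57), Zfp36l1 (-0.54) and Abhd17c (-0.45). The calls of Ighg2c, Cx3cr1 and Trem2 held whichever single library was left out. Ighg2b lost its call without MKO 2 (adjusted p = 0.0683), Osgin1 without any 1 of the control libraries (up to 0.0968). Igha lost it without control 2, control 3, MKO 2 or MKO 3 (up to 0.114). Gclc, Zfp36l1 and Abhd17c lost it without any library but MKO 1, and Cpeb2 without any library (up to 0.182).

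The count of 465 called genes fell to 243 without control 2, to 180 without MKO 2 and to 190 without MKO 3, with 238, 175 and 181 genes higher. In all, 156 calls (153 higher, 3 lower) held in all 6 fits with 1 library left out. The 13 genes lower became 6 without control 1, 5 without control 2, 31 without MKO 1 and 5 without MKO 2, and DESeq2 called 50. In 2960 genes (19.4%) the values of the genotypes did not overlap, where chance gives 10%. The authors' deposited table has 880 genes at an adjusted p under 0.05, 763 higher and 117 lower, with 463 of the 465 limma calls among them.

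**Figure D1:**
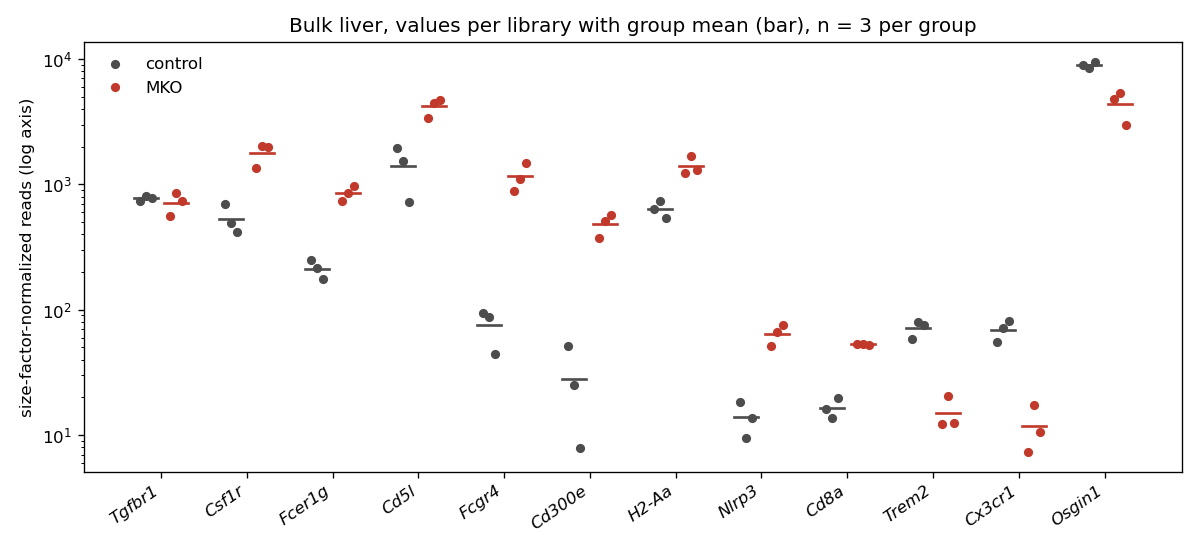
Normalised value (log axis) of 12 genes in each bulk liver, with control and MKO libraries as points and a bar at each group mean. Fcgr4 has means of 75 and 1162 and Trem2 of 71.4 and 15.0 in control and MKO livers, while the Tgfbr1 values of the genotypes overlap (560 to 857).

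Genes of macrophages in general were higher in MKO livers. Of 15 measured, 12 rose by limma and 14 when adjusted over the list alone, with a median log2 fold change of 1.5 (2.83-fold; camera adjusted p = 1.27e-14, adjusted p = 0.477 with an estimated correlation). Fcer1g, a signalling chain of Fc receptors, rose from 213 ± 37.2 to 859 ± 118, Csf1r, the receptor for the macrophage growth factor (chromosome 18, 61100598 to 61132149, + strand), from 534 ± 145 to 1790 ± 390.1, and Cybb, a subunit of the phagocyte oxidase, from 280.3 ± 33.8 to 980 ± 234. Laptm5 rose from 376 ± 48.0 to 1080 ± 167. Lyz2, the locus that drives the Cre, was the member with a negative value (-0.44 ± 0.31, adjusted p = 0.651); it lies outside the naming rule and was chosen after its values were seen. The calls of Fcer1g, Csf1r, Cybb and Laptm5 held in all 6 fits with 1 library left out.

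Among Kupffer cell identity genes, 5 of 20 rose by limma and 13 when adjusted over the list alone (median log2 fold change 1.34; camera adjusted p = 4.07e-08, adjusted p = 0.556 with an estimated correlation). Cd5l, a secreted Kupffer cell protein, rose from 1410 ± 633 to 4206 ± 716, Clec1b from 172 ± 39.6 to 420 ± 70.8, Spic, a transcription factor of iron-recycling macrophages, from 30.9 ± 13.4 to 138 ± 59.9, and Adrb1 by a log2 fold change of 2.59. The fifth, Timd4 (2.08), lies outside the naming rule and was chosen after its values were seen; it lost its call without any library but control 1 (up to 0.154). The calls of the other 4 were lost without MKO 2 or without MKO 3, with adjusted p up to 0.134. Those of Cd5l and Spic were also lost without control 2, and those of Cd5l and Adrb1 without MKO 1; edgeR called 3 of the 20 genes.

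Lipid-associated macrophage genes moved apart. By limma, Itgax (38.3 ± 6.14 to 106 ± 13.3) and Lgals3 (206 ± 44.1 to 480 ± 104) rose and Trem2 fell among 18 measured, with 4 higher and 4 lower when adjusted over the list alone and a median of -0.18 (camera adjusted p = 0.378). Gpnmb (chromosome 6, 49036546 to 49070929, + strand), a glycoprotein of these macrophages that lies outside the naming rule, was read at 205, 159 and 292 in controls and 39.1, 54.0 and 114 in MKO livers (-1.75 ± 0.38, adjusted p = 0.0501). The Itgax call was lost without MKO 3 (0.0570) and that of Lgals3 without control 2, control 3, MKO 2 or MKO 3 (up to 0.0818). Of 13 monocyte genes, Ms4a4c, Ms4a6c, Fcgr1 and Itgam rose and Cx3cr1 fell by limma, with 5 higher and 1 lower when adjusted over the list alone (median 0.5; camera adjusted p = 0.00558, adjusted p = 0.590 with an estimated correlation). Ms4a6c went from 72.8 ± 23.8 to 282 ± 96.0 and Ms4a4c from 11.8 ± 4.34 to 55.9 ± 6.39. Without control 3 or MKO 2 the camera p of the monocyte list was 0.0653 or 0.116. The calls of Ms4a4c, Ms4a6c and Fcgr1 were lost without MKO 2 or MKO 3, and those of Ms4a6c and Fcgr1 also without control 2 (up to 0.0788). Itgam (log2 fold change 2.06), outside the naming rule and chosen after its values were seen, lost its call without control 2 or MKO 2 (up to 0.0814).

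Inflammatory and antigen presentation genes were higher as well. Of 24 inflammatory mediators, 5 rose by limma and 10 when adjusted over the list alone (median 1.11; camera adjusted p = 1.52e-08, adjusted p = 0.556 with an estimated correlation). Nlrp3, an inflammasome sensor, rose from 13.9 ± 4.51 to 64.2 ± 12.1, Il1b from 61.8 ± 6.62 to 256 ± 130, Tnf from 7.05 ± 3.96 to 36.2 ± 13 and Nos2 from 1.74 ± 1.64 to 21.9 ± 9.51. The fifth, Ccl4 (2.51), lies outside the naming rule and was chosen after its values were seen; it lost its call without any library but control 2 (up to 0.209). Nlrp3 lost its call without MKO 2 or MKO 3 and Il1b without control 2 or control 3 (up to 0.0569), and Tnf and Nos2 without any library but control 1 (up to 0.191). Of 13 MHC class II genes, 6 rose and 10 when adjusted over the list alone (median 1.11; camera adjusted p = 3.51e-09, adjusted p = 0.396 with an estimated correlation). H2-Aa rose from 636 ± 94.8 to 1406 ± 247, H2-Ab1 from 1002 ± 138 to 2151 ± 499, Cd74 from 1752 ± 318 to 4196 ± 1274 and H2-DMb1 by a log2 fold change of 1.22. The H2-Aa call held in all 6 fits. H2-Ab1 lost it without control 3 or MKO 3 (up to 0.0541). Cd74 lost it without control 1, control 3, MKO 2 or MKO 3 (up to 0.0844) and H2-DMb1 without any library but control 1 (up to 0.115).

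Of 25 interferon-stimulated genes, 7 rose by limma and 17 when adjusted over the list alone (median 0.75; camera adjusted p = 2.47e-13, adjusted p = 0.399 with an estimated correlation). Gbp3 rose from 123 ± 22.2 to 355 ± 40.8 and Irf7, a regulator of interferon genes, from 621 ± 84.2 to 1244 ± 139; both calls held in all 6 fits. Gbp7 (1.26) lost its call without MKO 2 or MKO 3 (up to 0.0646) and Oasl2 (0.88) without control 2, control 3, MKO 2 or MKO 3 (up to 0.0909).

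Lymphocyte and dendritic cell markers moved with the genotype too. Of 27 T and NK cell genes, 4 rose by limma and 18 when adjusted over the list alone, with a median of 1.23 (camera adjusted p = 8.99e-17, adjusted p = 0.275 with an estimated correlation). Cd8a rose from 16.5 ± 3.04 to 52.9 ± 0.854, Gzmb, a cytotoxic granule protease, from 9.46 ± 3.56 to 50.1 ± 18.6, Cd3e by a log2 fold change of 1.40 and Il2rb by 1.29. The Cd8a call was lost without MKO 2 or MKO 3 (up to 0.0645), that of Gzmb without control 2, MKO 1 or MKO 3 (up to 0.0912), and those of Cd3e and Il2rb without any library but MKO 1 (up to 0.157). Of 14 dendritic cell genes, Batf3 (11.6 ± 4.04 to 80.6 ± 13), Wdfy4 (67.7 ± 18.7 to 230 ± 22.8) and Clec9a (41.9 ± 0.820 to 104 ± 6.48) rose, each also in all 6 fits, and 5 rose when adjusted over the list alone (median 0.71; camera adjusted p = 9.15e-07, adjusted p = 0.172 with an estimated correlation). Of 6 neutrophil genes Csf3r rose, as it did when adjusted over the list alone (79.3 ± 11.6 to 163 ± 15.2), with a list median of 0.45 (camera adjusted p = 0.0356, adjusted p = 0.590 with an estimated correlation). The Csf3r call was lost without control 2, MKO 2 or MKO 3 (up to 0.0895), and the neutrophil list's without those or control 3 (0.0512 to 0.346).

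Endothelial, stellate cell and matrix genes showed small shifts. Of 19 endothelial genes Pecam1 rose by limma (255 ± 44.9 to 498 ± 77.7), and 2 rose when adjusted over the list alone. The median was 0.27 (camera adjusted p = 1.35e-05, adjusted p = 0.590 with an estimated correlation). Pecam1 lost its call without control 2, control 3, MKO 2 or MKO 3 (up to 0.0858). Of 19 stellate cell genes 0 were called by limma, edgeR and DESeq2, 0 when adjusted over the list alone and 1 at an unadjusted p under 0.05. The median was 0.26 (camera adjusted p = 0.0125, adjusted p = 0.592 with an estimated correlation). Of 33 extracellular matrix genes 0 were called by limma, 0 when adjusted over the list alone, 4 at an unadjusted p under 0.05 and 1 by edgeR and by DESeq2. The median was 0.21 (camera adjusted p = 0.0257, adjusted p = 0.683 with an estimated correlation). Fn1 (-0.08) and Dcn (0.26) were their most abundant members. The list calls were lost without control 1 (0.165 for both), control 2 (0.0512 stellate, 0.263 matrix) or MKO 2 (0.117 and 0.178). Genes of endoplasmic reticulum and integrated stress had a median of -0.37 over 26 genes, with 3 members positive (camera adjusted p = 0.00104, adjusted p = 0.590 with an estimated correlation). None passed limma's test alone or when adjusted over the list alone, 4 passed at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 1. Hsp90b1 stood at -0.23, and without control 2 the list's p was 0.0512. Each library was scored by the mean log2 value of the stress list's members minus the mean of the 6 libraries. The scores were 0.18, 0.60 and -0.23 in control 1 to 3 and -0.08, -0.16 and -0.31 in MKO 1 to 3. Control 3 thus lay within the MKO range.

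The remaining lists did not pass camera's test with all 6 libraries. Of 20 genes of the TGF-beta pathway Tgfb1, a ligand, rose by limma (151 ± 27.1 to 300.02 ± 55.0) and 3 rose when adjusted over the list alone (median 0.05, camera adjusted p = 0.374). Of 24 efferocytosis and lysosome genes, Axl (390 ± 30.8 to 914 ± 179), Mertk (465 ± 44.7 to 714 ± 28.4) and Abcg1 (log2 fold change 1.05) rose, the same number as adjusted over the list alone (median 0.09, 0.0872). Of 18 fetal and tumour genes, Cdkn2a (4.12 ± 1.92 to 43.9 ± 7.31), Axl and Cd44 (1.36) rose, 3 also when adjusted over the list alone; their median was -0.08 but their mean 0.22 and camera's direction up (0.410). Of 19 glucose metabolism genes the glycolytic Pkm (353 ± 23.4 to 737 ± 136) and Hk2 (1.35) rose, 2 also when adjusted over the list alone (median -0.17, 0.613). Of 22 NRF2 target genes G6pdx (81.4 ± 4.08 to 180 ± 15.7) rose and Gclc fell, with 1 and 1 when adjusted over the list alone (median -0.22, 0.110). Of 17 immediate early genes Klf2 rose (1.0), 1 also when adjusted over the list alone; the median was 0.00, the mean -0.03 and camera's direction down (0.965). The efferocytosis and lysosome list passed without MKO 1 (0.00985), and the NRF2 list without control 1 (0.0431), without MKO 3 (0.0322) and with the replicate block (0.0399). With control 3 and MKO 1 both left out, a choice made after seeing the data, the efferocytosis and lysosome (0.0198), fetal and tumour (0.0149) and TGF-beta pathway (0.0235) lists passed. The calls of Axl, Cdkn2a and G6pdx held in all 6 fits. Pkm lost its call without MKO 2 (0.0568) and Abcg1 without any 1 of the MKO libraries (up to 0.0908). The calls of Tgfb1, Mertk and Cd44 were lost without control 2, control 3, MKO 2 or MKO 3 (up to 0.141). Klf2 lost its call without any library but control 1 (up to 0.144) and Hk2 without any but MKO 1 (up to 0.157).

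In the other lists 0 members were called by limma. Medians were -0.10 for 30 hepatocyte genes (Alb -0.02; camera adjusted p = 0.356), -0.10 for 25 fatty acid oxidation genes (Fabp1 -0.10; 0.159), -0.01 for 26 lipogenesis genes (Scd1 -0.25; 0.965), -0.08 for 24 cholesterol synthesis genes (0.218), -0.13 for 24 bile acid genes (Slco1b2 -0.60; 0.159) and -0.36 for 21 acute phase genes (Hpx 0.02; 0.0964). They were -0.38 for 14 bile duct genes (0.0534), 0.13 for 28 cell division genes (Pcna -0.09; 0.206), -0.25 for 5 red blood cell genes (Hbb-bs -0.15; 0.0663), 0.01 for 10 mitochondrial transcripts (mt-Co1 -0.00; 0.884), -0.02 for 18 clock genes (Nr1d1 -0.17; 0.965), -0.14 for 15 sex-dimorphic genes (Cyp2d9 -0.14; 0.474) and 0.36 for 15 B and plasma cell genes (Ighm -1.89; 0.378). Some of these lists passed camera's test with a library left out, in the direction of all 6: bile duct genes without control 1 (0.00140) or control 2 (0.00382), red blood cell genes without control 2 (0.00121), cell division genes without control 1 (8.85e-05), acute phase and hepatocyte genes without control 3 (1.13e-11 and 0.0386) and fatty acid oxidation genes without MKO 2 (0.0467). Bile duct genes also passed on RLE-scaled reads (0.0470), and bile duct and acute phase genes with the replicate block (0.0275 and 0.0293). Without control 3, however, the camera adjusted p of bile duct genes was 0.914. Their score, formed as for the stress genes above, was 1.15 in control 3 and -0.309 to -0.146 in the other libraries. The lower bile duct median thus rested on control 3. When adjusted over the list alone, 1 clock gene was higher and 1 lower, 2 B and plasma cell genes were higher and 1 lower, and the others kept 0. At an unadjusted p under 0.05 these lists held 0 to 5 members. edgeR called 1 clock gene, and DESeq2 called 1 bile acid gene, 2 clock genes and 3 B and plasma cell genes. The mean and median differed in sign for clock genes (mean 0.12, camera up), lipogenesis (0.04, up), mitochondrial transcripts (-0.00, down) and sex-dimorphic genes (0.17, camera down). Of genes of other tissues 2 were measured and 0 called, with Cfd at 1.21. Saa1, outside the naming rule and chosen after its values were seen, was at 581 in control 3, against 32019 and 28635 in control 1 and 2 and 2153 to 3175 in MKO livers. With control 3 and MKO 1 left out, a choice made after seeing the data, limma called 399 genes, 360 higher and 39 lower, and acute phase genes passed camera's test (8.86e-08).

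**Figure D2:**
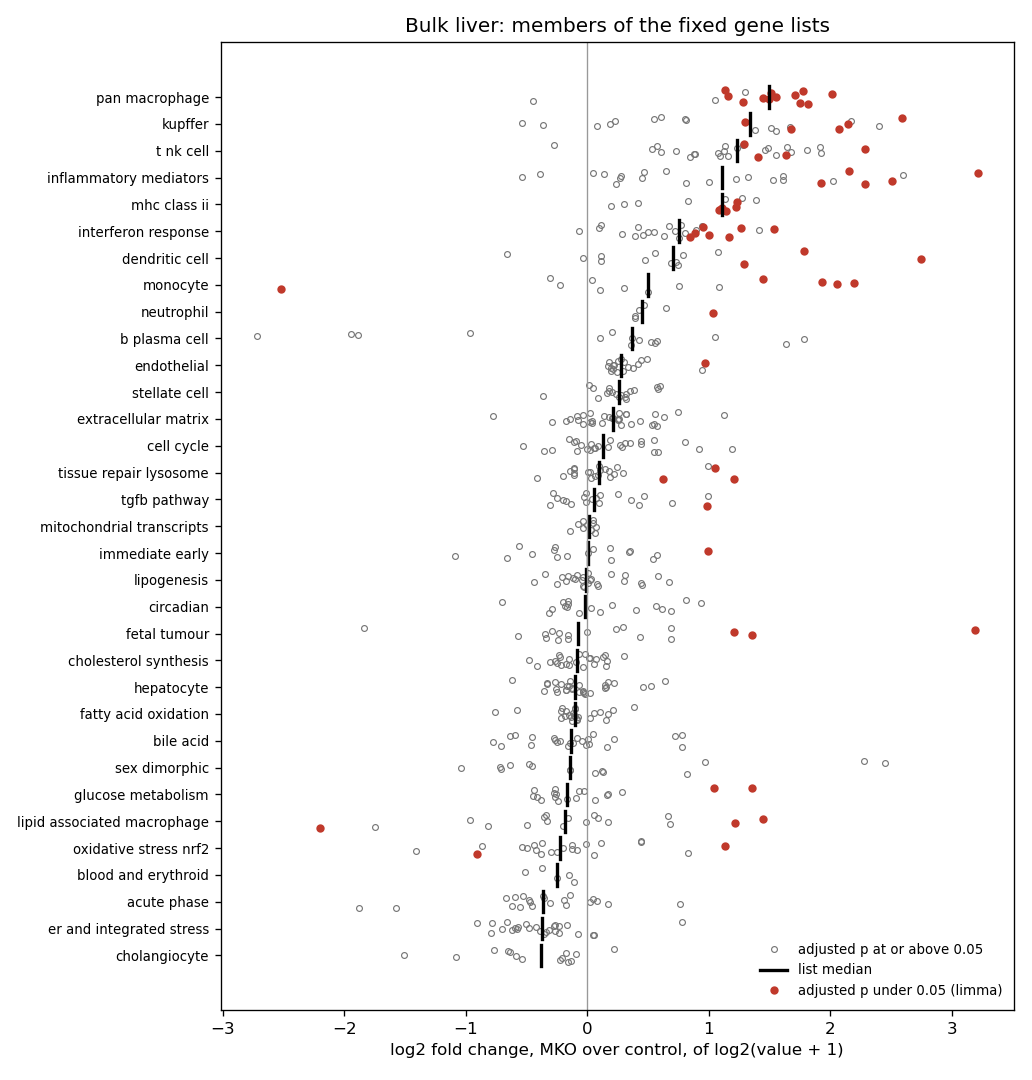
Log2 fold change (MKO over control) of each measured member of 33 fixed gene lists as points, filled in red where limma's adjusted p lay under 0.05, with a bar at each list median. The highest medians are those of the general macrophage (1.5), Kupffer cell (1.34) and T and NK cell (1.23) lists; with an estimated correlation 0 lists passed and 4 had an unadjusted p under 0.05.

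In the nuclei, Tgfbr1 was highest in the macrophage-like cluster of the control pool and lower there in the MKO pool. The value was 13.5 per 10000 in control and 4.87 in MKO macrophage-like nuclei (log2 ratio -1.45, 0.367-fold). It was 10.3 and 6.98 in the dendritic-like cluster, 6.88 and 4.15 in an unnamed cluster led by Top2a and Mki67, and 2.84 and 2.13 in stellate-like nuclei. The T and NK-like cluster had 2.61 and 2.23, the B-like cluster 1.5 and 2.07, and the bile duct-like cluster 1.31 and 1.56. In the 3 hepatocyte-like clusters control values were 1.12 to 1.25 and MKO values 0.996 to 1.11. They were, in the endothelial-like clusters 1.11 and 0.699 against 0.822 and 0.724, and in an unnamed cluster led by Igfbp5 1.29 and 0.587. There was 1 pool per genotype, so none of these differences has a replicate check.

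Macrophage-like nuclei of the MKO pool had lower values of lipid-associated genes and higher values of Kupffer and general macrophage genes. Of 8 lipid-associated genes kept by the filter all but Ctsl (1.22 and 1.77; outside the naming rule and chosen after its values were seen) were lower, with a median log2 ratio of -1.08, at percentile 0.00 of the random lists. Gpnmb was at 6.14 in control and 1.18 in MKO, Colec12 at 3.99 and 0.747, Atp6v0d2 at 2.69 and 0.730 and Mmp12, a macrophage elastase, at 3.52 and 1.03. Of 10 Kupffer cell genes 9 were higher (median 0.36, percentile 98.7), with Cd163 at 1.03 and 2.46, Id3 at 1.37 and 2.58, Nr1h3 at 1.74 and 3.20 and Clec1b at 1.11 and 1.89. Of 13 general macrophage genes 12 were higher (median 0.45, percentile 99.6), with Fcer1g at 3.15 and 8.24, Tyrobp at 1.92 and 4.41 and C1qc at 2.94 and 5.22, while Lyz2 was at 6.58 and 2.65. Below the filter, and chosen after their values were seen, Trem2 was at 0.809 and 0.0829 and the monocyte list members Cx3cr1 at 1.32 and 0.192 and Ccr2 at 1.39 and 0.343.

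The highest ratios in this cluster were those of Fcrl5 (0.127 and 5.71), Ccser1 (0.0758 and 2.28), Clec2g (0.0772 and 2.28), Gm15987 (0.653 and 8.07), Negr1 (2.92 and 30.3), Itgad (0.0295 and 1.5), Ccnd2 (0.157 and 2.18) and Cd300e (0.229 and 2.46). The lowest were Fgf13 (4.30 and 0.137), Apbb2 (2.26 and 0.106), Mef2c, a transcription factor (3.37 and 0.325), Nav2 (4.71 and 0.591), Pcdh7 (1.57 and 0.122), Myo5a (4.08 and 0.553), Blnk (2.60 and 0.383) and Ldlrad4, an inhibitor of TGF-beta signalling (3.54 and 0.577). TGF-beta pathway genes had a median of -0.28 with 2 of 7 positive (percentile 9.20); Ski was at 1.76 and 0.693, Skil at 3.17 and 2.07 and Tgfbr2 at 3.22 and 2.63. MHC class II genes had a median of -0.14 with 1 of 6 positive (percentile 33.1), with Ciita, the regulator of class II genes, at 1.55 and 0.690, Cd86 at 4.84 and 2.99, H2-Aa at 4.41 and 3.85 and Cd74 at 7.13 and 9.20. Among monocyte and inflammatory genes Itgam was at 1.59 and 2.26, Ms4a6c at 2.41 and 3.37, Il18 at 1.26 and 2.50, Ccl6 at 1.33 and 2.05 and Il1b at 2.72 and 2.69. Hp, a monocyte list member that hepatocytes also express abundantly, was at 2.80 and 4.69, in a cluster where hepatocyte genes had a median of 0.54. Of the 452 genes higher in bulk 240 were kept in this cluster, and 180 of them (75%) were higher in the MKO pool. Among the 1869 kept genes tested in bulk, these 240 included, the share was 42.8%. Whether the pooled livers came from the mice of the bulk libraries is not given in the sample titles. The nuclei may therefore not be an independent check.

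**Figure D3:**
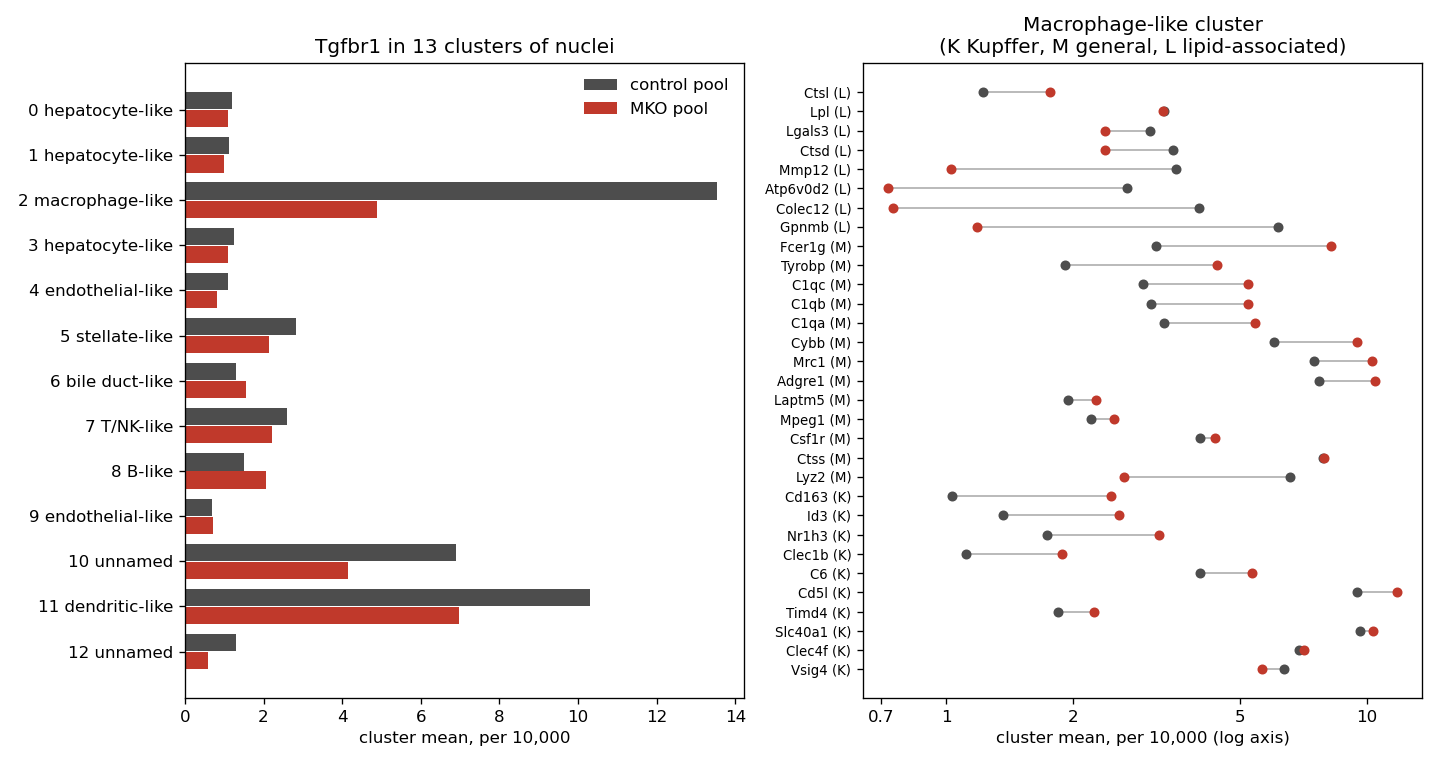
Cluster means per 10000 in the control and MKO pools, for Tgfbr1 in 13 clusters as bars (left) and for Kupffer (K), general macrophage (M) and lipid-associated (L) genes in the macrophage-like cluster as points on a log axis (right). Tgfbr1 is at 13.5 and 4.87 in the macrophage-like cluster, where Gpnmb is at 6.14 and 1.18 and Fcer1g at 3.15 and 8.24; there are no error bars because each genotype is 1 pool.

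Hepatocyte genes were higher in the MKO pool in all 13 clusters, with list medians of 0.31 to 0.95, including the macrophage-like cluster (12 of 15 positive, median 0.54), where Alb, outside the naming rule and chosen after its values were seen, was at 27.3 and 39.6. Over the clusters not hepatocyte-like Alb lay between 16.95 and 50.3 in the control pool and between 32.3 and 72.6 in the MKO pool, against 24.7 to 62.6 and 45.7 to 68.8 in the hepatocyte-like ones. Values of hepatocyte genes outside hepatocyte-like nuclei, Hp in the macrophage-like cluster included, were therefore read as background from free RNA and not as expression. The same holds for Rbp4, at 2.03 and 11.5 in the dendritic-like cluster (7.87 to 8.87 and 14.6 to 15.1 in hepatocyte-like ones). Ghr may be background too, with 35.3 to 84.1 and 15.7 to 68.7 in hepatocyte-like clusters. It was at 4.56 and 1.17 in the T and NK-like cluster, where Alb was at 50.3 and 72.6. More free RNA in the MKO pool would not lower Ghr, and the cause of its fall was not tested. In hepatocyte-like nuclei Cyp2b9 (2.22 and 13.4) and Cyp2c70 (0.290 and 2.22) led 1 cluster, Bhmt (3.75 and 40.4) another and Serpina1e (2.66 and 9.13) the last, while Adgrv1 was at 6.71 and 1.39, Rad51b at 26.2 and 3.0 and Cth, an enzyme of cysteine synthesis, at 17.4 and 2.36. How much free RNA adds to values within hepatocyte-like clusters was not tested, and the range of Alb there overlapped that of the other clusters. Stellate-like nuclei had Ccl2, a monocyte chemoattractant, at 0.228 and 1.33 and Wt1 at 1.87 and 0.652, and stellate genes had a median of 0.23 (percentile 99.6). Endothelial-like nuclei had Vcam1, an adhesion molecule, at 0.506 and 1.45 and H2-D1 at 2.67 and 6.96, and endothelial genes had a median of 0.10 (11 of 15 positive, percentile 98.9) in 1 endothelial-like cluster and -0.31 (3 of 11 positive, percentile 3.36) in the other. In the T and NK-like cluster Ctla4, an inhibitory receptor, was at 0.962 and 3.79 and Mir155hg at 0.571 and 2.65, and T and NK genes had a median of 0.30 (percentile 99.95). In the B-like cluster Cdh18 was at 2.51 and 0.0623, and MHC class II genes had a median of 0.33 (percentile 99.2). Bile duct-like nuclei had Kcnip4 at 58.4 and 12.6, and Dmbt1 was listed at 0 in the control pool and at 5.44 in the MKO pool. In the Top2a cluster Hbb-bs was at 0.214 and 13 (0.0411 to 0.734 in the other clusters of the MKO pool) and Fgf13 at 8.11 and 0.672, and in the dendritic-like cluster Agbl1 was at 6.63 and 0.197.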

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

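The tests with control 3 and MKO 1 both left out, and limma on rescaled reads, were chosen after the result was seen; the other alternatives were fixed before the data were examined. The count of called genes, 465, lay between 399 and 684 except where single libraries were left out (180 to 441, with 175 to 410 higher and 5 to 31 lower), and 0 calls changed sign. The 13 lower genes became 50 with DESeq2, 34 at an adjusted p under 0.1 and 39 with 2 libraries left out together. edgeR called 494 genes with TMM and 505 with RLE, and limma on rescaled reads 478 and 477. The replicate numbers showed no clear pairing of the samples. After each gene's genotype mean was subtracted, the remaining values of same-numbered libraries correlated at 0.06, -0.03 and -0.11. Replicate 1 alone correlated best with its own number. With 3 libraries per genotype these correlations cannot settle whether the samples were paired. With the replicate block 408 genes (391 higher, 17 lower) and 16 lists passed. Of 33 lists, 13 passed, against 0 with an estimated correlation, 5 with fry and 10 to 14 with single libraries left out. Called named genes kept their call in 861 pairs of gene and setting and lost it in 163, with 0 changes of sign; those not called changed sign in 23. The shallowest library was MKO 1, with 17448117 reads, and limma recovered 2 of 67 simulated genes at 1.5-fold, so changes of that size are mostly missed. Ratios in the macrophage-like nuclei kept their direction under the other filter, pseudocount and centring: Tgfbr1 from -1.47 to -1.38, lipid-associated genes from -1.15 to -1.01, Kupffer genes from 0.31 to 0.43 and general macrophage genes from 0.45 to 0.52. The ranges were 0.27 to 0.54 for monocyte genes, -0.45 to -0.21 for TGF-beta pathway genes and -0.15 to -0.07 for MHC class II genes. Of the monocyte list only Hp, Itgam and Ms4a6c passed the main filter, all higher in the MKO pool, and Hp was read as background. Cx3cr1 and Ccr2, below that filter and chosen after their values were seen, were lower. The monocyte range therefore gives no direction for monocyte genes as a whole.

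The direction of some lists turned. The cause was not tested. Adjusted p-values with single libraries left out ran from 1.13e-11 to 0.703 for acute phase genes, 0.0513 to 0.888 for B and plasma cell genes, 8.85e-05 to 0.712 for cell division, 0.222 to 0.993 for clock genes, 0.0386 to 0.861 for hepatocyte genes, 0.434 to 0.874 for immediate early genes, 0.476 to 0.923 for lipogenesis and 0.116 to 0.788 for mitochondrial transcripts. With 2 libraries left out together they were 0.351 for B and plasma cell genes, 0.826 for cell division, 0.214 for clock genes and 0.302 for fatty acid oxidation, and with fry 0.963 for immediate early genes. Uncalled genes turned too, as log2 fold changes with single libraries left out: Tgfbr1 -0.271 to 0.0353, Hpx -0.395 to 0.364, Pcna -0.237 to 0.0406, Fn1 -0.275 to 0.132, Fabp1 -0.201 to 0.000436, Alb -0.0992 to 0.143 and mt-Co1 -0.100 to 0.125. With 2 libraries left out together the values were 0.0376 for Tgfbr1, -0.222 for Hpx and 0.0148 for Hbb-bs. On recovered reads Hpx stood at -0.0801 (edgeR, TMM), -0.0721 (RLE) and -0.0744 (DESeq2), and mt-Co1 at 0.0115, 0.0183 and 0.0158, with 0.00599 for limma on RLE-scaled reads.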

Other observations

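The tests of explanations and of other splits of the libraries, the division of B from plasma cell genes and the genes outside the naming rule were chosen after the result was seen. The fixed list of B and plasma cell genes held members of both signs in bulk liver. By limma 0 of 15 passed, with 5 at an unadjusted p under 0.05, 0 called by edgeR and 3 by DESeq2. Its 10 B cell members had a median log2 fold change of 0.54, with 10 positive. Its plasma cell members were the 5 measured of Jchain, Mzb1, Ighm, Igkc, Iglc2, Tnfrsf17 and Pou2af1. Their median was -1.89, the value of Ighm, with 1 positive. Igkc, Iglc2 and Pou2af1 were also among the leading genes of the B-like cluster, so this set does not mark plasma cells alone. With single libraries left out the medians ran from 0.22 (without MKO 1) to 0.72 and from -2.39 (without control 3) to -1.03 (without control 2). Jchain, which joins secreted antibodies, was read at 54.3, 268 and 51.2 in control and 23.2, 5.10 and 17.3 in MKO livers (-2.72 ± 0.71, limma adjusted p = 0.101). Igkc and Ighm were highest in control 2, at 994 and 2550. In the B-like nuclei Jchain was at 1.6 in the control pool and 0.158 in the MKO pool.

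The MKO pool also differed in an unnamed cluster of nuclei led by the dividing-cell genes Top2a and Mki67. General macrophage genes had a median log2 ratio of 1.70 there (9 of 10 positive) and endothelial genes one of -1.96 (1 of 5 positive). Clec4f was at 1.89 and 4.33 and Fcgr4 at 0.326 and 3.22. Hepatocyte genes were higher there too (12 of 12 positive, median 0.95). The cluster was enriched for 9 general macrophage, 4 Kupffer and 10 cell division genes, so it may hold more than 1 cell type. A change in its mix of cells cannot be told from a change in expression. MKO 3 stood apart with Ren1 at 1631, against 33.7 to 145 elsewhere, and Marco at 2985, against 82.8 to 1206.

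The bulk rise of macrophage genes may come from more macrophages, from more of these transcripts in each, or both. A lower share of hepatocyte RNA is excluded as the whole cause, since stellate, endothelial and bile duct genes had medians from -0.38 to 0.27 against 1.5 for macrophage genes. A change within each macrophage alone stays open: the bulk median over 13 genes exceeded the median within macrophage-like nuclei by 1.07 (1.52 against 0.45), but nuclei and whole tissue differ in RNA and the pools have no replicates.

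Lyz2 did not rise with the other general macrophage genes. Its difference from their median in bulk was -1.95 (-0.44 against 1.51), and its log2 ratio in macrophage-like nuclei was -1.27. LysMcre is inserted in Lyz2, and its carriers may therefore make fewer Lyz2 transcripts; fewer lipid-associated macrophages could give the same values. These cannot be told apart, since every MKO library carries the Cre.

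MKO 1 had high values of some genes of the female liver pattern: Cyp2b9 4844 (145 to 389 elsewhere), Cyp2b13 510.2 (2.17 to 13.6), Cux2 355 (6.51 to 31.8) and Cyp2a22 3643. Cyp2d9, the most abundant member of the fixed sex-dimorphic list, did not stand apart, at 13377 in MKO 1 and 12924 to 19665 elsewhere. Female tissue is excluded by Xist, at 10.98 against 4.20 to 22.4 in the other libraries, and Ddx3y at 1335. A control library under a wrong label is excluded too: in 97.3% of the 410 genes called higher without MKO 1, it exceeded all 3 controls. In the MKO pool the first hepatocyte-like cluster also had more Cyp2b9 (2.22 and 13.4) and Cyp2b13 (0.0625 and 0.919). Cyp2a22 was at 0.741 and 0.936 there and at 0.244 and 0.112 in another hepatocyte-like cluster. No biological explanation was tested.

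The 6 bulk libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 465 genes, 452 higher and 13 lower, and the highest other 4; 1 of the 10, the real one, gave as many in each case. For lists 5 of the 10 splits gave at least the 13 of the real one, and the highest other gave 18. The number of lists passing camera with the preset correlation thus does not set the genotypes apart from other splits. Those camera p-values, however small, do not by themselves show an effect of genotype.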
